A study of Mus musculus with 4 samples.

How the data were processed

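ATAC-seq peak lists of 4 mouse thymocyte samples were analysed, 2 of DN and 2 of DP cells. Per the submitters' processing notes, reads were aligned to mm10, and the tools named are Bowtie2 and Picard, without versions or roles. The peak caller is known here only from the name PeakDEck in the names of the deposited lists. Its settings, the read filters, the treatment of duplicate and mitochondrial reads and any shift of the insertion sites are not given in the sources used here. Each sample has its own list, so peaks were called per sample. Each deposited list gives, per peak, chromosome, start, end, a name and a p-value, which is the authors' own value. The p-values ran from 1e-12 to 0.000601, 0.000540, 0.000487 and 0.000890 in DN 1, DN 2, DP 1 and DP 2, took 24 to 39 distinct values per list, and were tied at the largest value in 35.4, 44.2, 29.1 and 38.5% of peaks. They were used only to rank and filter peaks within a list. Peaks start on a grid of 50 bp and are at least 300 bp wide. The lists carry no read counts, so depth is unknown, and a peak missing from a list cannot be told apart from a site with too few reads. No confidence intervals that need counts were computed.

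Groups and replicate numbers came from the sample labels. No list was a copy of another: 1.34 to 6.26% of the shorter list's peaks had identical coordinates in the other list. This cannot exclude repeat preparations or sequencing runs of 1 sample. Peaks on chromosomes 1 to 19, X and Y from the 4 lists were merged into regions when they shared at least 1 bp. A region is DN-only when both DN lists and neither DP list hold it, DP-only in the opposite case, and shared when all 4 lists hold it.

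Gene positions came from a RefSeq gene table of GRCm38, the same build as mm10. It holds 21883 protein-coding genes with start and end but no strand. The planned distance to the nearest transcription start site was therefore replaced by the distance to the nearest end of a protein-coding gene span, within 100 kb, and a region at a gene end has its midpoint within 1000 bp of either end. Receptor loci were bounded by their annotated segments. The planned comparison of 20 sequence motifs was not run, since no genome sequence was used here. Coordinates are counted from 1.

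Lists of regions or genes were compared with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment at 0.05 within each family (loci, gene lists, chromosomes). These tests compare the 4 lists; regions and genes are not replicates. With 2 samples per group only 3 splits exist, so an exact permutation test cannot go below p = 0.333. Before the data were examined, 16 gene lists were fixed with 225 distinct genes, all 225 of which are in the gene table; Trdc and Trgc1 are receptor segments outside its protein-coding genes and could not be assigned a region. The genes named were fixed by rule at the same time. The rule takes the 12 genes with the highest and the 12 with the lowest DN-only minus DP-only count, and always Il2ra, Ptcra, Notch1, Notch3, Hes1, Rag1, Rag2, Cd4, Cd8a, Bcl11b, Cd3e, Tcf7 and the receptor loci; 1 further gene that the rule always names is not reported here. It allows list members to be named with their counts, up to 4 leaning ones per list, and the text names only part of these, at least 1 of those with the largest difference in each list that has leaning members. It also takes the 5 DN-only and 5 DP-only regions of best mean rank.

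Alternatives fixed before the data were examined were the top 50% of each list, lists limited to the length of the shortest, a 50% overlap, merging within 250 bp, leaving out each list in turn (the remaining list then stands for its group), gene spans widened by 10 kb, distal regions alone, gene ends within 500 or 2500 bp, and the replicate number as a block. Added after the data were examined were the test of DP-leaning genes among genes with a reproducible region, 10000 matched random lists, enhancer intervals and parts of Igh, peaks per 10000 peaks, 11 gene families, and a comparison of Igh with chromosome 12 regions matched on peak rank and gene-end class, and the leading list members under the settings above. The procedure was tested on simulated lists built from the real regions (85294 simulated regions): 196 of 200 planted DN-only and 196 of 200 planted DP-only regions were recovered, among 244 and 250 called. Each planted or common region was placed in every list of its group, so sites missed by a list were not simulated. In the data 77281 regions came from a single list, and the recovery does not cover calls that such misses make or lose. On 5913 leaning genes with shuffled leans, 5.75% of 400 random lists had p under 0.05 in the gene list test, and 100 of 100 planted lists with 14 of 20 genes leaning DN passed. Lists planted toward DP, the direction of most genes, were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.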

Results

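Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 4 thymocyte samples of wild-type C57BL/6J mice aged 5 to 7 weeks. Of these, 2 samples were CD4- and CD8-negative double-negative (DN) cells sorted as CD25-positive, which covers the stages in which the T cell receptor beta chain (Tcrb) is rearranged. The other 2 were CD4- and CD8-positive double-positive (DP) cells, the later stage in which the alpha chain (Tcra) is rearranged. The 4 deposited peak lists held 38808 and 33131 peaks for DN 1 and DN 2, and 39718 and 70385 peaks for DP 1 and DP 2. They covered 16.98, 13.21, 19.04 and 30.29 Mb of the mm10 genome. Read depth is unknown, because the lists carry no read counts. Nothing in the labels says whether the 2 samples of a group came from separate animals, so the spread between them may be technical.

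The series asks how antigen receptor enhancers act in developing lymphocytes, so the receptor loci were compared first. The V part of Tcrb (chromosome 6, 40891296 to 41281990) held more peaks in DN cells, with 21.5 ± 3.54 (SD, n = 2) against 11 ± 2.83 in DP cells. It contained 5 regions present in both DN lists and in neither DP list (DN-only regions), and 0 regions of the opposite kind (DP-only regions). Of these 5 regions, 4 overlapped a V segment: Trbv2, Trbv5, Trbv12-1 and Trbv24. Trbv12-1 was also overlapped by a region that all 4 lists held (41112751 to 41113700). Trbv5 was also overlapped by a region that DN 1, DN 2 and DP 1 held (41062601 to 41063200). The Tcra loci showed the opposite picture. The Tcra V part (chromosome 14, 52427967 to 53977678) held 45 ± 9.90 peaks in DP cells against 2.5 ± 0.71 in DN cells. It contained 20 DP-only and 0 DN-only regions, and 15 of the 20 overlapped a V segment. Among these 15 were regions over the delta chain V segments Trdv1 and Trdv2-2, which lie in the same interval. The Tcra J-C part (54155005 to 54224198) held 21 and 11 peaks in the DP lists and 0 in each DN list. All 7 of its reproducible regions were DP-only, and 5 of them overlapped a J segment: Traj49, Traj47, Traj42, Traj37 and Traj36.

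Both Tcrb D segments lay in regions that all 4 lists held (chromosome 6, 41532551 to 41534000 for Trbd1 and 41541351 to 41543600 for Trbd2), and the Tcrb D-J-C part held 5.5 ± 2.12 peaks in DN and 7.5 ± 0.71 in DP cells (n = 2 each), which is 1.506 ± 0.42 and 1.505 ± 0.72 per 10000 peaks. The D-J-C part of the delta chain locus, nested inside Tcra, held a DN-only region over the D segment Trdd2 (chromosome 14, 54122001 to 54123200). This region was also the second best ranked of all DN-only regions. The gamma chain locus Tcrg (chromosome 13, 19178042 to 19352343) held 9 ± 4.24 peaks in DN and 2 ± 1.41 in DP cells, with 2 DN-only regions (19219201 to 19220050, which lay 2583 bp from Trgc1, and 19322651 to 19323200) and 0 DP-only regions. The immunoglobulin heavy chain locus Igh, which is rearranged in B cells, held 128 ± 26.9 peaks in DP and 12 ± 5.66 in DN cells (chromosome 12, 113256204 to 116009954). It contained 52 DP-only and 0 DN-only regions. Of the 52, 50 lay in the V part and 30 lay within 500 bp of a segment. The light chain locus Igk held 35.5 ± 13.4 peaks in DN and 29 ± 18.4 in DP cells, which overlap as counts but not per 10000 peaks of a list (6.70 and 13.6 in DN against 4.03 and 5.97 in DP), with 4 DN-only and 1 DP-only regions.

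**Figure D1:**
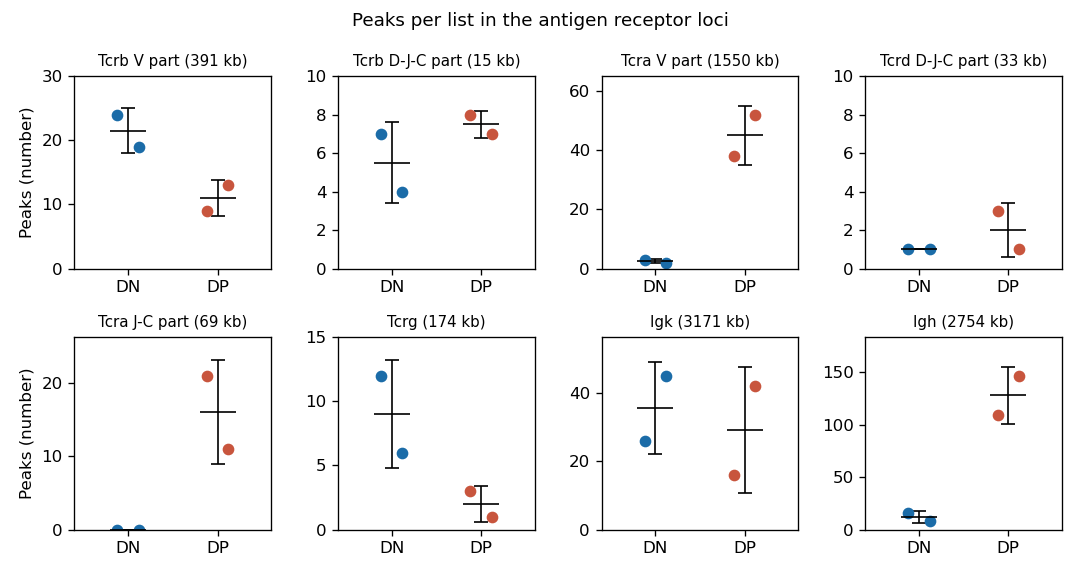
Number of peaks (vertical axis) per peak list in each of the 8 receptor intervals, with DN lists in blue and DP lists in red; the horizontal bar is the group mean and the error bar 1 SD (n = 2). DN lists hold 24 and 19 peaks in the Tcrb V part against 9 and 13 in DP lists, and in the Tcra V part, Tcra J-C part and Igh each DP list lies above each DN list.

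Against the rest of the genome, where 25.2% of the DN-only and DP-only regions together were DN-only, 4 of the 7 loci with such regions passed a two-sided test with Benjamini-Hochberg adjustment. By Fisher's exact test these were Igh (adjusted p = 2.84e-06), the Tcrb V part (adjusted p = 0.00358), the Tcra V part (adjusted p = 0.00926) and Igk (adjusted p = 0.0283). Fisher's exact test gave an adjusted p of 0.0892 for Tcrg, 0.237 for the Tcra J-C part and 0.252 for the Tcrd D-J-C part. In each of these loci every DN-only or DP-only region was already of 1 class. At these numbers of regions the test could not pass in that direction, so it does not show that the lists are alike there. The test compares these 4 lists, and regions are not replicates. It was not matched for chromosome or distance to gene ends, by which the DN-only share differed. On chromosome 6, which holds Igk and Tcrb, that share was 30.7%. Single lists moved some calls, but leaving out a list also moves the genome background, since the remaining list then stands for its group. Without DN 1, 18233 regions counted as DN-only, against 2703 with all lists. Without DP 1, 44383 counted as DP-only, against 8006. A call gained or lost can thus come from the background and not from the locus. The Tcra V part kept 95.2 to 100% DP-only regions whichever list was left out, and the Tcrb V part had 40% without DP 1. Without DN 1 the Tcrb V part had 12.5% DP-only regions (Fisher's exact adjusted p = 0.240), while the Tcra J-C part passed (0.00470). Without DN 2 the Tcra J-C part (0.00143) and Tcrg (0.0439) passed. Without DP 1 the Tcra V part (0.170) and Igk (0.170) no longer passed while Tcrg did (0.0116), and without DP 2 Igk did not pass (0.267). Igk went from 20% to 86.5% DP-only without DP 1, and its DN minus DP peaks turned from 6.5 to -6.5. The Tcrd D-J-C part went from 0% DP-only to 50% without DP 1 and 75% without DP 2, without passing. In the top 50% of each list the Tcra V part (0.0714), and with merging within 250 bp Igk (0.0719), did not pass Fisher's exact test after adjustment.

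**Figure D2:**
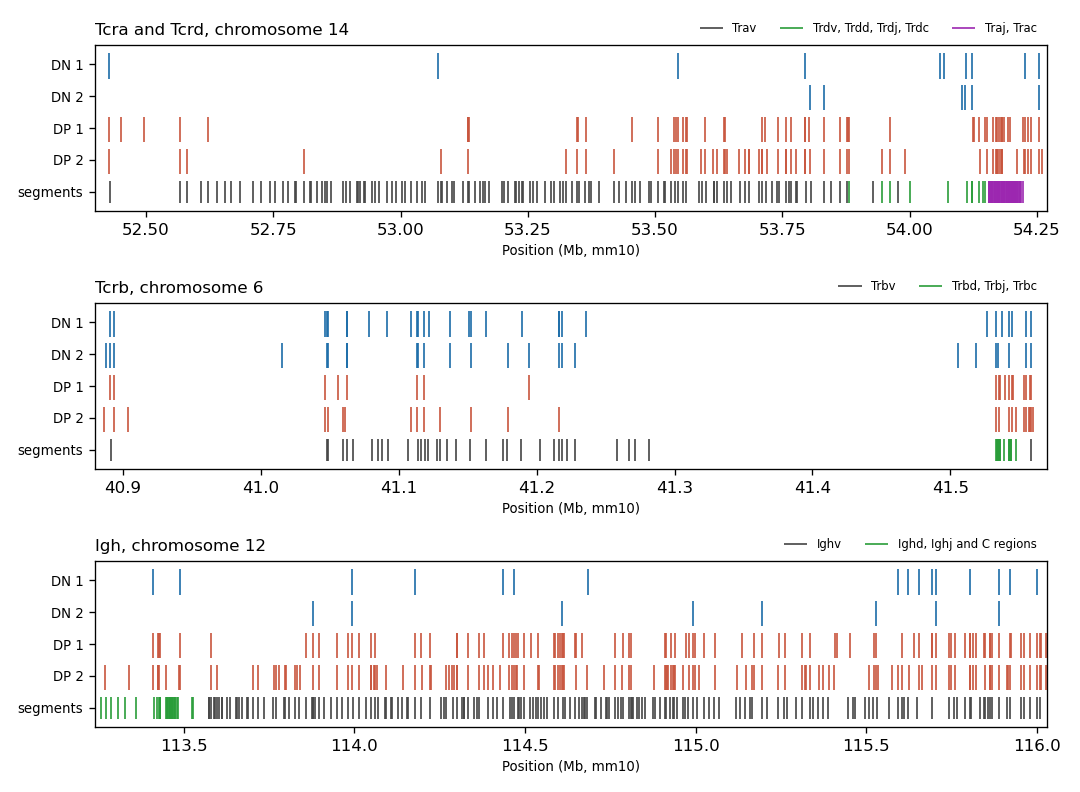
Positions of peak regions (vertical lines) in each of the 4 lists along Tcra with Tcrd, Tcrb and Igh, in Mb of mm10, above the annotated receptor gene segments. In the Traj and Trac interval DP lists hold peaks and DN lists hold 0, and in the Tcrb V part DN lists hold more lines than DP lists.

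Short intervals known to contain receptor enhancers were added after the data were examined. Between Trbc2 and Trbv31, where the Tcrb enhancer lies, all 4 lists shared a region (chromosome 6, 41554051 to 41555200), and 2 further regions were DP-only, of which 1 overlapped Trbv31. The interval held 1 ± 0 peaks in DN and 3.5 ± 0.71 in DP cells (n = 2). The Tcra enhancer lies between Trac and Dad1. The interval used ran from Trac to the far end of Dad1 (chromosome 14, 54224199 to 54253929) and so took in the Dad1 gene. In it DN lists held 0.5 ± 0.71 and DP lists 4 ± 0 peaks. Its 2 DP-only regions lay 8903 and 14703 bp from Trac, the farther one inside Dad1. A region nearer to Trac (chromosome 14, 54227051 to 54228100) was held by DN 1 and both DP lists. Not counted was a region at the far end of Dad1 (54253701 to 54254300), which all 4 lists held. Its midpoint lay 72 bp past the interval. Fisher's exact test against the genome gave p = 1 for both intervals. Each held only 2 DP-only and 0 DN-only regions, against a mostly DP-only genome, so the test could not pass toward DP.

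Across the genome the 4 lists merged into 107621 regions, of which 7955 were shared by all 4 lists, 8006 were DP-only and 2703 were DN-only. Most of the rest, 77281 regions, came from a single list. The other 2 ways of splitting the samples into pairs gave fewer regions held by exactly the 2 lists of a pair: 843 and 927 for DN 1 with DP 1 against DN 2 with DP 2, and 1807 and 308 for DN 1 with DP 2 against DN 2 with DP 1. The Jaccard index, the shared share of the regions of a pair of lists, was 0.296 for the DP pair and 0.233 for the DN pair. Between groups it ranged from 0.136 (DN 2 with DP 2) to 0.263 (DN 1 with DP 1), so DN 1 overlapped DP 1 more than DN 2. Within-group pairs exceeded between-group pairs by 0.0714 on average (exact permutation p = 0.333, the smallest that 3 splits allow). The difference was 0.141 without DN 1 and 0.0150 without DP 2. With 1 list standing for its group the classes grew. DN-only regions numbered 18233 without DN 1 and 17338 without DN 2. DP-only regions numbered 44383 without DP 1, 19337 without DP 2 and 13269 without DN 1, and shared regions 13199 without DN 2.

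**Figure D3:**
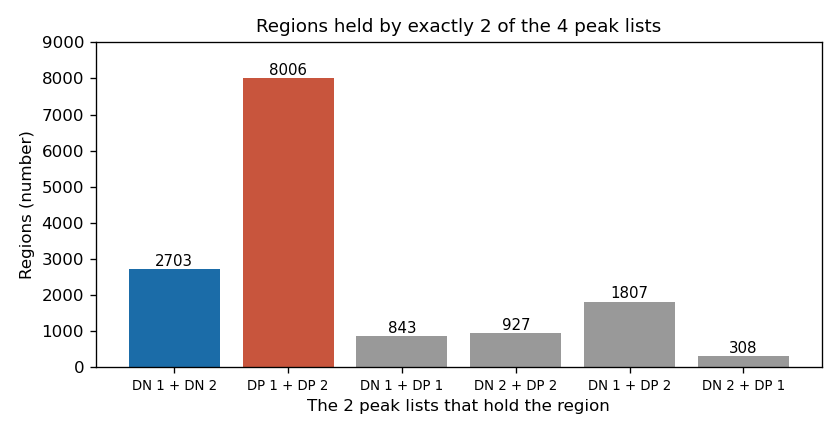
Number of regions (bars) held by exactly the 2 peak lists named under each bar, of the 4 lists. The bars of the DP pair (8006) and the DN pair (2703) stand above the 4 pairs that mix the groups, which lie between 308 and 1807.

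Most genes fixed as markers of the DP stage had DP-only regions. Each region was assigned to the protein-coding gene with the nearest end within 100 kb, and a gene leaned DP when it had more DP-only than DN-only regions. Of 12145 genes with a region in both lists of a group, 4707 leaned DP and 1206 leaned DN. Among 30 genes of the DP stage, 23 leaned DP and 1 (Cd69) leaned DN. Cd8b1, the CD8 beta chain, had 7 DP-only regions and 11 ± 1.41 peaks in DP against 0.5 ± 0.71 in DN lists (n = 2). Cd8a had 5 DP-only regions, with 5.5 ± 0.71 against 0 peaks, and Cd4 had 2, with 3.5 ± 0.71 against 0.5 ± 0.71. Satb1, a chromatin organiser of thymocytes, had 7 DP-only regions and 20 ± 2.83 against 1.5 ± 2.12 peaks. Ets2 had 6, with 11 ± 0 against 1.5 ± 0.71. Rag1 and Rag2, the recombinase genes, each had 1 DP-only and 1 shared region. Some of these counts moved with single lists or settings, given here as DN-only minus DP-only regions. Satb1 had -14 without DP 1, -17 without DP 2, -4 in the top 50% of each list or with lists limited to the shortest length, and -3 with gene spans widened by 10 kb. Ets2 had -3 with lists of the shortest length and -1 with widened spans. Rag1 had -4 without DP 1 and -2 without DP 2, Rag2 had -6 without DP 1 and -2 without DN 1 or with widened spans, and both had 0 in the top 50%. Cd4 had -4 with widened spans and -1 with merging within 250 bp. Cd69 had 0 without DN 1 and turned to -2 without DP 1 or DP 2.

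Of 20 pan-T identity genes, 16 leaned DP and 0 leaned DN. Bcl11b, Lef1 and Runx1, transcription factors of T cells, had 5 DP-only regions each. Bcl11b held 16.5 ± 2.12 peaks in DP and 4 ± 2.83 in DN lists (n = 2). Cd3e had 0 regions of either class, with 3.5 ± 2.12 against 1 ± 0 peaks. DN-only minus DP-only regions of Bcl11b moved from -5 to -12 without DP 1, -8 without DN 1 or DP 2, and -3 in the top 50% or with lists of the shortest length. Without DP 1 Lef1 had -10 and Runx1 -15, without DP 2 Lef1 had -9, and without DN 1 Runx1 had -8. Cd3e had -1 without DN 2, without DP 1 or in the top 50%, and -2 without DP 2.

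Genes of the CD25-positive DN stages also carried DP-only regions: of 25 such genes 12 leaned DP, and 2 (Bcl11a and Lmo2) leaned DN with 1 DN-only region each. Il2ra, which encodes the CD25 used to sort the DN cells, had 3 DP-only, 1 shared and 0 DN-only regions, with 8 and 2 peaks in the DN lists and 9 in each DP list. Its DN-only minus DP-only difference of -3 became -1 without DN 2 or with lists limited to the shortest length, -6 without DN 1 and -5 without DP 2. Ptcra, the pre-T cell receptor alpha chain, had 0 regions of either class. Tcf7 had 3 DP-only regions, with 11 ± 0 against 1.5 ± 2.12 peaks. Notch3 had 3, with 4 ± 0 against 0.5 ± 0.71, and Notch1 had 1, with 5 ± 0 against 1.5 ± 2.12. Hes1, a Notch target, had 2 DP-only regions, but 1 more DN-only than DP-only region without DN 2. Of 18 Notch pathway genes, 9 leaned DP, led by Igf1r with 4 DP-only regions, and 2 (Rbpj and Jag1) leaned DN with a difference of 1. DN-only minus DP-only regions of Tcf7 were -5 without DN 1 and -7 without DP 1 or DP 2. Notch1 had -4 without DN 1, -2 without DP 2 and 0 with lists of the shortest length, and Notch3 had -1 with those lists or in the top 50%. Hes1 also had -5 without DP 1, 0 in the top 50%, and -1 with the shortest length or distal regions alone, and Igf1r had -12 without DP 1 and -2 without DN 2. Ptcra had -1 with widened spans. Leans toward DN depended on single lists. Bcl11a had 3 without DN 1 or DN 2, -5 without DP 1 and 0 without DP 2, and Lmo2 had 2 without DN 2 and 0 without DP 1. Rbpj had 0 without DN 1 and 4 without DN 2, and Jag1 had 3 without DN 1 and 0 without DP 1 or DP 2.

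In the remaining lists of T cell biology, 15 of 21 T cell receptor signalling genes leaned DP, among them Nfatc1 and Nfatc2 with 5 DP-only regions each, and 2 (Cd69 and S1pr1) leaned DN. S1pr1, the receptor for thymic exit, had 3 DN-only and 1 DP-only regions and held 12 ± 0 peaks in DN against 5.5 ± 0.71 in DP lists (n = 2). DP-leaning and DN-leaning genes numbered 9 and 1 of 12 markers of mature single-positive cells, 11 and 1 of 16 interleukin and chemokine receptor genes, 12 and 0 of 20 cell cycle genes, and 6 and 0 of 12 V(D)J recombination genes. In the lists of other cell types and of housekeeping genes the numbers were 2 and 0 of 12 B cell markers, 3 and 0 of 14 myeloid markers, 2 and 2 of 12 NK and innate lymphoid markers, 4 and 0 of 9 gamma-delta markers that are protein-coding, 0 and 0 of 10 erythroid markers, 3 and 2 of 12 stromal markers, and 2 and 0 of 12 housekeeping genes. The members with the most DP-only regions were Ifngr1 among receptors and Cebpb among myeloid markers, with 5 each. Runx3 (mature cells), Ccnd3 (cell cycle), Hmgb1 (recombination), Eomes (NK) and Ywhaz (housekeeping) had 4 each. Sox4 had 3 among gamma-delta markers, Epcam and Pecam1 had 2 among stromal markers, and Ebf1 and Pax5 had 1 among B cell markers.

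These counts, as DN-only minus DP-only regions, also moved with single lists. Without DP 1 they were -12 for Nfatc1, -8 for Ifngr1 and Eomes, -7 for Runx3 and Ywhaz, -6 for Sox4, -4 for Pecam1, Ebf1 and Pax5, and 1 for S1pr1. Without DP 2 they were -8 for Nfatc1 and Ifngr1, -5 for Sox4 and -3 for Ebf1. Without DN 1 Ccnd3 had -7 and S1pr1 4, and without DN 2 S1pr1 had 7, Pecam1 -1 and Ebf1 0. In the top 50% of each list Nfatc1 had -3, Nfatc2, Hmgb1 and Sox4 had -1, Runx3, Ccnd3, Ifngr1 and Cebpb had -2, and Ebf1 and Pax5 had 0. With lists of the shortest length Nfatc2 had -3 and Hmgb1 -2. With widened spans Nfatc2 and Ifngr1 had -3, Runx3 and Ywhaz -2, Cebpb, Eomes and Sox4 -1, and Hmgb1, Epcam and S1pr1 0.

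By group mean, lists called in DN cells held fewer gene ends in general, and in 15 of the 16 gene lists. For B cell, erythroid and housekeeping genes, though, a DN list held as many as a DP list. A peak lay within 1000 bp of an end of 31.3 ± 7.67% of the 21883 protein-coding genes in DN and of 47.3 ± 2.08% in DP lists (n = 2). For pan-T genes these shares were 22.5 ± 10.6% and 75 ± 7.07%. The DP-stage genes gave 40 ± 14.1% and 91.7 ± 7.07%, and the CD25-positive DN-stage genes 34 ± 19.8% and 60 ± 11.3%. Housekeeping genes gave 70.8 ± 17.7% and 83.3 ± 0%. Myeloid markers were the exception, with 14.3 ± 10.1% in each group.

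The planned test set DN-leaning against DP-leaning genes of each list, against the same split in all other leaning genes, of which 79.6% leaned DP. With two-sided Fisher's exact tests, 0 of 15 lists passed the Benjamini-Hochberg adjustment and 1, the DP-stage list, had an unadjusted p under 0.05 (0.0440). The test could not have passed a list toward DP at these sizes. If all leaning members of a list leaned DP, 13 of the 15 lists would stay at an unadjusted Fisher's exact p of 0.05 or more, and the lowest adjusted p would be 0.128. The DP-stage and pan-T lists passed Fisher's exact test without DN 1 or without DN 2, and the cell cycle list passed without DN 1. Leaving out a list also changes the background of other leaning genes. Without DN 2, DN-leaning genes numbered 3994, against 1206 with all lists. Such calls can thus come from the background and not from the list. An added Fisher's exact test, chosen after the results were seen, compared the share of DP-leaning genes among those with a reproducible region. It passed for 5 of 16 lists: DP stage (76.7% against 38.7% of other genes, Fisher's exact adjusted p = 0.000510), pan-T (84.2%, 0.000510), receptor signalling (71.4%, 0.0156), mature single-positive (81.8%, 0.0184) and interleukin and chemokine receptors (73.3%, 0.0246). Set against random lists matched on the number of reproducible regions per gene, 0 of 16 lists passed after adjustment and 2 had an unadjusted p under 0.05, pan-T (permutation p = 0.0054) and mature single-positive (0.0352). The DP-stage and pan-T calls of the added test held without any 1 list. The mature single-positive call ended without any 1 list (Fisher's exact adjusted p from 0.119 to 0.927), the receptor signalling call without DP 1 (0.336), and the interleukin and chemokine receptor call without DP 1 (0.672) or DP 2 (0.388). Without DN 2 the cell cycle list passed the added Fisher's exact test (adjusted p = 0.0177). The receptor signalling call also ended in the top 50% of each list (0.146), with distal regions alone (0.167) and with gene spans widened by 10 kb (0.0766).

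Ranked by DP-only minus DN-only regions, the leading DP genes were Prex1, an exchange factor for Rac, with 11 DP-only regions and 16.5 ± 0.71 peaks in DP against 0.5 ± 0.71 in DN lists (n = 2), and Dad1, with 10. Dad1 is the nearest protein-coding gene to the Tcra J-C part, and with gene spans widened by 10 kb in place of the nearest end it had 2. Fyn, a kinase of receptor signalling, and LOC115488016 had 9 DP-only and 1 DN-only regions each. Galnt2 and St8sia1 had 8, Nck2 had 8 and 1 DN-only, and Gins2, Irf2bp2, Itpr2 and Maml3 had 7. With widened spans the DP-only excess fell to 7 for Prex1, 4 for Nck2 and Irf2bp2, 1 for LOC115488016 and 0 for Gins2. In the top 50% of each list it was 4 for Prex1, Galnt2, Gins2 and Maml3, 3 for Fyn and Irf2bp2, 5 for St8sia1 and 6 for Dad1, and with lists of the shortest length 5 for St8sia1 and 4 for Itpr2 and Maml3. Without DN 2 it was 4 for Fyn and Nck2. Without DN 1 it was 11 for Nck2 and Itpr2 and 12 for Irf2bp2. Without DP 1 it was 17 for Itpr2, 15 for St8sia1, 14 for Nck2, 13 for Maml3 and 12 for Irf2bp2, and without DP 2 it was 16 for Dad1 and 12 for Nck2 and Itpr2. The leading DN gene was Pcmtd1, with 5 DN-only regions and 9.5 ± 0.71 peaks in DN against 2 ± 0 in DP lists. Ednrb, an endothelin receptor, Efna5, an ephrin, Gm1966, Negr1, Pam, Prex2 and Stxbp6 had 4 each. Slc8a1, a sodium-calcium exchanger, had 4 and 1 DP-only, and Adgb, Bckdhb and 2210010C04Rik, which lies inside the Tcrb V part, had 3. Peak numbers did not always go with these leans. Prex2 held 7 ± 1.41 peaks in DN and 13 ± 15.6 in DP lists, Slc8a1 10.5 ± 2.12 and 15.5 ± 14.8, Negr1 21.5 ± 0.71 and 21 ± 17.0, Efna5 8 ± 1.41 and 7.5 ± 4.95, Stxbp6 11.5 ± 0.71 and 10.5 ± 7.78, and Pam 10 ± 1.41 and 8.5 ± 2.12. The means were 7.5 ± 0.71 and 4 ± 1.41 for Ednrb, 8.5 ± 2.12 and 3.5 ± 0.71 for Gm1966, 11.5 ± 2.12 and 7 ± 1.41 for 2210010C04Rik, 6 ± 1.41 and 4 ± 1.41 for Adgb, and 7 ± 1.41 and 4.5 ± 3.54 for Bckdhb. Of the leading DN genes only Prex2 and Slc8a1 had the higher mean in DP lists. For Negr1, Efna5, Stxbp6, Pam and Bckdhb the excess in DN lists was within the SD of the DP lists. With widened spans the DN-only excess fell to 3 for Pcmtd1, 2 for Ednrb and Gm1966 and 0 for 2210010C04Rik. Several of these DN genes rested on DP 1. Without it Ednrb had equal numbers, and DN-only minus DP-only regions became -4 for Efna5, -18 for Negr1, -2 for Pam, -16 for Prex2, -9 for Stxbp6, -16 for Slc8a1 and -2 for Bckdhb. Gm1966 had 2 without it, and Adgb and 2210010C04Rik had 1. Negr1 also turned (-2) without DP 2, when Stxbp6 had 0 and Efna5 and Pam had 2. Without DN 1 Negr1 had 15, Stxbp6 8, Slc8a1 7 and Bckdhb 6, and without DN 2 Negr1 had 12, Pam 7 and 2210010C04Rik 6. In the top 50% Pcmtd1 had 3, Ednrb and Pam had 2 and 2210010C04Rik had 1, as it had with merging within 250 bp. The numbers of leaning genes moved too: DN-leaning genes numbered 2980 without DN 1, 3994 without DN 2 and 485 without DP 1, and DP-leaning genes 10207 without DP 1 and 7315 without DP 2.

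DN-only regions lay farther from gene ends than DP-only regions. Of DN-only regions 7.33% had their midpoint within 1000 bp of an end of a protein-coding gene, against 26.4% of DP-only and 51.6% of shared regions. The median distance was 45069 bp for DN-only, 8768 bp for DP-only and 764 bp for shared regions. Regions outside these classes, mostly from a single list, lay at a gene end in 6.61%, close to the DN-only share, with a median distance of 77646 bp. The odds ratio of a gene end, DN-only against DP-only, was 0.220 (two-sided Fisher's exact p = 2.1e-113). It was 0.0623 without DN 1, 0.131 without DN 2 and 0.521 without DP 2, and it was 1.00 without DP 1 (Fisher's exact p = 0.946), when each of the 44383 regions that the longest list held and both DN lists lacked counted as DP-only.

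By chromosome, the DN-only share of DN-only and DP-only regions was lowest among the autosomes and X on chromosome 11 (8.31%, Fisher's exact adjusted p = 1.26e-30), followed by 19 (14.1%), 9 (14.3%), 15 (17.3%) and 7 (21.2%), while chromosome Y held 0 DN-only and 3 DP-only regions. It was above the other chromosomes on 3 (42.3%, Fisher's exact adjusted p = 1.50e-19), 18 (37.5%), 14 (33.2%) and 6 (30.7%). These 9 of 21 chromosomes passed the two-sided Fisher's exact test after Benjamini-Hochberg adjustment, 5 lower and 4 higher. Without DN 1 or DN 2, 8 chromosomes were higher, and without DP 2, 2 were. With each list limited to the length of the shortest, 7 were higher.

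**Figure D4:**
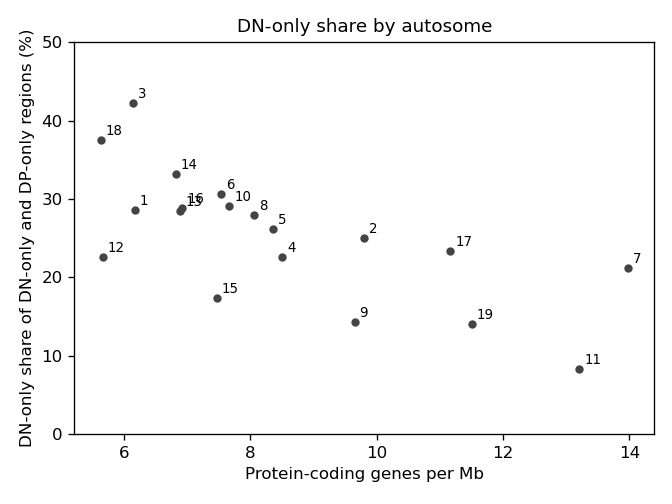
DN-only share of the DN-only and DP-only regions (percent, vertical axis) against protein-coding genes per Mb (horizontal axis) for the 19 autosomes, each point labelled with its chromosome number. Chromosome 11 has the lowest share (8.31%) and chromosome 3 the highest (42.3%).

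The best ranked single DN-only regions, by mean rank of their p-value within the lists, were on chromosome 18 (21299901 to 21300850, outside gene spans and 237 bp from an end of Garem1), on chromosome 14 (the Trdd2 region above), on chromosome 3 (20304601 to 20305450, 9447 bp from Agtr1b), on chromosome 7 (88536651 to 88537350, 45429 bp from Rab38) and on chromosome 18 (59174951 to 59176150, inside Chsy3). The best ranked DP-only regions were on chromosome 7 (114562301 to 114563300, inside Cyp2r1), chromosome 2 (122903301 to 122904300, 94248 bp from Sqor), chromosome 11 (87108501 to 87109450, 262 bp from Prr11) and chromosome 6 (50596351 to 50597350, inside 4921507P07Rik, and 99643201 to 99644100, inside Eif4e3). No replicate spread applies to these single regions, each of which is present or absent in a list.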

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

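Of the tests below, the circular shifts, the gene density relation and the ribosomal protein genes were chosen before their results were seen, and the top 50% of the lists, the label swap, the B cell markers and both chromosome 12 comparisons after. Outside the chromosomes compared, the lists held peaks on the mitochondrial chromosome, 7 in DN 1, 8 in DN 2 and 9 in each of DP 1 and DP 2, which stand out as signal outside the main measurement.

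DN-only regions lay far from gene ends. Chance overlap of noise peaks is argued against, since with the DN 2 list moved along each chromosome the highest DN-only count of 100 circular shifts was 205 against 2703 in the data. Weak peaks at the end of the lists are argued against too, because in the top 50% of each list 8.73% of DN-only and 34.6% of DP-only regions were at a gene end. Peak calls of the DN libraries tilted toward gene-poor sequence stay a candidate explanation: across 19 autosomes the DN share of regions held by a single list fell with gene density (Pearson r = -0.53, permutation p = 0.02, Spearman rho = -0.50, permutation p = 0.03, r = -0.43 without the 2 chromosomes farthest from the median density). A difference in accessible chromatin between DN and DP cells also stays open, untested.

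Of the CD25-positive DN-stage genes, 12 leaned DP, Il2ra among them, and 2 leaned DN, a DP share of 85.7% against 79.6% of other leaning genes (two-sided Fisher's exact p = 0.748, and 0.0885 had all leaned DP, so the test could not pass toward DP). A swap of DN and DP labels is argued against by the Tcra J-C part, where lists labelled DN held 0 peaks and those labelled DP at least 11. Lower detection of regions at active genes in the DN lists may account for part of it. A peak lay at an end of 49.5 ± 10.6% of 100 genes with ribosomal protein symbols (Rpl, Rps) in DN and 80.5 ± 0.71% in DP lists (n = 2), a difference of -31 percentage points. The genes were picked by symbol alone, so the set may hold genes of other kinds or genes not active in these cells. The fixed housekeeping list differed less, with 83.3% in DN 1, 58.3% in DN 2 and 83.3% in each DP list. Of its genes with a reproducible region 16.7% leaned DP, against 38.8% of other genes (two-sided Fisher's exact adjusted p = 0.258). How much of the lean lower detection accounts for was not measured. Opening of these genes in DP cells stays open, untested.

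Igh held 52 DP-only and 0 DN-only regions. B cells in the DP samples are argued against, since 0 of 12 B cell markers had a peak at a gene end in both DP lists and in neither DN list (8.33 ± 0% of them had one in DN and 12.5 ± 5.89% in DP lists, n = 2), although Ebf1 and Pax5, the 2 markers that leaned, had 1 DP-only region each. Lower detection in the DN lists as elsewhere on chromosome 12 is argued against as the whole cause: of 69 Igh regions held by both DP lists, 75.4% were in no DN list, against 38.1% of 919 on the rest of the chromosome (two-sided Fisher's exact p = 2.54e-09), and 48.1% was the mean for regions matched on DP rank and on lying at a gene end (permutation p = 0.0001, highest permuted share 69.6%). Reads shared between near-identical V segments could not be tested without a sequence. Accessible Igh V segments in DP thymocytes remain a hypothesis.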

How the results depend on the processing

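The added list test, the leading list members, the peaks per 10000 peaks and the enhancer intervals were chosen after the data were examined; the settings below were fixed before. Across all settings, with the later peaks per 10000 peaks included, 455 of 555 values of main results stayed. Of the rest 27 moved, 22 lost and 17 gained a call, and 34 turned direction. Tested values stayed when they kept their direction and side of the threshold. Counts were judged by a fixed ratio. Jaccard and peak differences were judged by direction and the spread of the main result, or per 10000 peaks by direction alone. Of 407 values of named genes 272 stayed, 126 moved and 9 turned (8 genes). Of these, 36 of the 126 moves belong to the replicate block, whose 37 values are sums of peak differences and not numbers of regions, so their size does not compare; the 370 region values gave 271, 90 and 9. The cause was not tested except where the setting's construction gives it: leaving out a list lets the other stand alone, which raises the number of regions in its group. A 50% overlap, gene ends within 500 bp and gene ends within 2500 bp changed no call. Motif alternatives were not run, and depth, unknown here, limits what an absent peak means.

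In the top 50% of each list, the within-group excess of the Jaccard index was 0.127, and DN minus DP peaks were -67 in Igh, -23.5 in the Tcra V part (DP-only share 100%, Fisher's exact adjusted p = 0.0714), -6.5 in the Tcra J-C part, 2.5 in Tcrg, 0.5 in the Tcrb D-J-C part and 1 in the Tcrd D-J-C part. DP-leaning shares of genes with a region lost the call for receptor signalling (60%) and mature single-positive genes (75%), gained it for DN-stage genes (75%), and turned for B cell (0%), NK (57.1%) and V(D)J genes (27.3%); the planned test turned for myeloid markers (80%). With lists limited to the shortest length, DN minus DP peaks were -72 in Igh, -28 in the Tcra V part and 0.5 in the Tcrd D-J-C part, 7 chromosomes had a higher DN-only share, and the mature single-positive call ended (72.7%). With merging within 250 bp Igk lost its call (33.3% DP-only), and DN-stage (70%), Notch (68.8%) and cell cycle genes (68.4%) gained one in the added test. With spans widened by 10 kb, Notch genes gained it (75%), receptor signalling (66.7%), interleukin and chemokine receptor (66.7%) and mature single-positive genes (72.7%) lost it, and NK (44.4%) and housekeeping genes (41.7%) turned. With distal regions alone, receptor signalling (65%) and mature single-positive genes (77.8%) lost it and stromal genes turned (40%).

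With the replicate number as a block (a gene leans when both same-numbered pairs differ the same way), 851 genes leaned DN and 5539 DP. Whether the numbers mark pairs could not be told. Same-numbered samples deviated with r = 0.0207 over all regions, but most regions came from a single list, and only 2 pairs exist. Over regions held by both lists of a group r was 0.0403. That value carries no information on pairing, since such a region has a difference of 0 within that group by definition. In this replicate block the added test took its shares among genes with any region, not only a reproducible one. These shares and calls therefore do not compare directly with those of the other settings. The added test called DN-stage (60%) and cell cycle genes (60%) and no longer mature single-positive genes (63.6%). It turned for NK (54.5%), housekeeping (33.3%) and stromal genes (30%). The planned test, which called 0 lists, turned for NK (100%), interleukin and chemokine receptor (84.6%), mature single-positive (77.8%) and myeloid genes (60%). Paired DN minus DP peaks in the Tcrb V part were 15 and 6. Of the named genes, Efna5, Negr1, Pam, Prex2, Stxbp6, Slc8a1, Adgb and Hes1 had no lean with the block, since their same-numbered pairs did not both differ in 1 direction.

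Leaving out each list in turn gave these ranges. DN-only regions numbered 3130 to 18233, DP-only 8974 to 44383 and shared 8358 to 13199, DN-leaning genes 485 to 3994 and DP-leaning genes 4412 to 10207. The Jaccard excess ranged from 0.0150 to 0.141, the gene-end odds ratio from 0.0623 to 1.00 and chromosomes with a higher DN-only share from 2 to 8. DP-only shares were 2.63 to 86.5% in Igk, 95.2 to 100% in the Tcra V part, 100% throughout in the Tcra J-C part, 0 to 40% in the Tcrb V part, 0 to 75% in the Tcrd D-J-C part and 0 to 20% in Tcrg. In the planned test DP shares of leaning genes were 61.1 to 95% for DN-stage, 95.8 to 100% for DP-stage, 94.4 to 100% for pan-T, 53.8 to 92.9% for Notch, 77.8 to 95% for receptor signalling, 85.7 to 100% for cell cycle, 84.6 to 91.7% for interleukin and chemokine receptor, 77.8 to 90% for mature single-positive, 60 to 83.3% for myeloid, 60 to 100% for NK, 50 to 100% for B cell and 50 to 100% for gamma-delta genes. In the added test DP-leaning shares were 66.7 to 90.5% for receptor signalling, 63.2 to 73.7% for cell cycle, 73.3 to 86.7% for interleukin and chemokine receptor, 63.6 to 81.8% for mature single-positive, 42.9 to 62.5% for myeloid, 37.5 to 90.9% for NK, 0 to 50% for erythroid and 42.9 to 71.4% for stromal genes. They were 16.7 to 41.7% for housekeeping, 33.3 to 80% for B cell, 33.3 to 75% for gamma-delta and 54.5 to 81.8% for V(D)J genes. DN-stage genes gave 50 to 82.6%, Notch genes 46.7 to 72.2%, DP-stage genes 76.7 to 96.7% and pan-T genes 85 to 100%. DN-only minus DP-only regions ranged from -4 to 5 for Efna5, -18 to 15 for Negr1, -2 to 7 for Pam, -16 to 6 for Prex2, -9 to 8 for Stxbp6, -16 to 7 for Slc8a1, -2 to 6 for Bckdhb and -5 to 1 for Hes1.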

Other observations

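All tests here were chosen after the data were examined. Gene families taken by symbol differed in how their genes leaned. Of the olfactory receptor genes that leaned, 22 leaned DN and 9 DP, against 79.9% DP among all other leaning genes (two-sided Fisher's exact test, adjusted p = 1.8e-08 over 11 families). Vomeronasal receptors gave 9 DN and 2 DP (Fisher's exact adjusted p = 8.04e-05), and protocadherins and cadherins 16 DN and 6 DP (9.63e-07). Genes with ribosomal protein symbols (Rpl, Rps), a set that may hold genes of other kinds, gave 1 DN and 31 DP (Fisher's exact adjusted p = 0.0362). The other 7 families did not pass. A second Fisher's exact test compared the share of DP-leaning genes among those with a reproducible region. It passed for olfactory receptors (14.8% against 38.9% of other genes, Fisher's exact adjusted p = 0.000314), vomeronasal receptors (10.5%, 0.0346) and zinc finger genes (22.5% against 39.2%, 1.10e-08). It did not pass for protocadherins and cadherins (19.4%, 0.0737) or ribosomal protein genes (41.3% against 38.7%, Fisher's exact adjusted p = 0.778). These leans were not tested apart from the lower number of gene ends in the DN lists. Only 61 of 1110 olfactory and 19 of 355 vomeronasal receptor genes had a reproducible region. Genes lying side by side were counted separately, and the p-values make no allowance for that.

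Counted per 10000 peaks of a list, the Tcrb V part held 5.96 ± 0.32 peaks in DN and 2.06 ± 0.30 in DP lists, Tcrg 2.45 ± 0.91 and 0.45 ± 0.43, the Tcra V part 0.69 ± 0.12 and 8.48 ± 1.54, the Tcra J-C part 0 and 3.43 ± 2.63, Igh 3.27 ± 1.21 and 24.2 ± 4.64, and Igk 10.1 ± 4.87 and 5.00 ± 1.37 (SD, n = 2 each). Each DN list lay above each DP list in the Tcrb V part, Tcrg and Igk, and below in the Tcra V part, the Tcra J-C part and Igh. The Tcrb D-J-C part (1.506 ± 0.42 and 1.505 ± 0.72) and the Tcrd D-J-C part (0.28 ± 0.03 and 0.45 ± 0.43) overlapped.

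Shared regions ranked ahead of group-specific regions within each list. Their median rank by p-value was at 13.4, 16.8, 14.2 and 7.78% of the list in DN 1, DN 2, DP 1 and DP 2. DN-only regions had medians of 35.6 and 30.7% in DN 1 and DN 2, and DP-only regions 42.5 and 26.0% in DP 1 and DP 2.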
